A study of Arabidopsis thaliana with 8 samples.

How the data were processed

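Total RNA from whole 2-week-old Arabidopsis thaliana seedlings of the Columbia-0 ecotype was measured on 8 one-colour (Cy3) Agilent arrays, 4 of wild type and 4 of plants carrying 35S:MYB87-SRDX. Per the labels, each sample held 5 seedlings. Nothing in the labels says whether the samples of a group were grown on separate plates, so the p-values measure the spread between these samples, which may be partly technical. The precision is limited by the number of arrays.

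The deposited scanner tables hold spot intensity values on a linear scale, made with Agilent Feature Extraction 9.1.3.1 per the submitters' processing notes. The processed signal was used for the main results. The authors' deposited value table holds, for each probe, the same processed signal intensity times a constant, with a factor of 0.001094 on the wild-type slide and 0.001175 on the MYB87-SRDX slide. These factors were found by dividing the values of that table by the scanner values. Its columns are therefore linear and not scaled between arrays within a slide, and their medians were 0.129, 0.15, 0.123 and 0.105 for wild type and 0.108, 0.133, 0.114 and 0.114 for MYB87-SRDX. Why the constants differ between the slides is not given in the sources used here.

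Each array held 37685 non-control spots of 37478 probes, of which 23 probes were spotted 10 times. Spots carrying an outlier flag were set to missing, between 3 and 44 spots per array. The log2 processed signal of each array was reduced by that array's 75th percentile over non-control spots, and spots of a probe were averaged. A probe was kept when it was well above background on at least 3 arrays of a group, and the brightest kept probe stood for a locus. Between 63.1% and 65.5% of spots were well above background per array, and 1 spot was saturated, on MYB87-SRDX replicate 3. Of 25665 loci on the array, 25449 were matched to the TAIR10.1 gene table used for symbols, and 20336 loci were tested, of which 9020 have a symbol in that table. For 445 tested loci several probes passed, and for 3 of these the probes passed the threshold in opposite directions. A further 8812 probes are named only by a genome position, whose build is not stated, and 2430 carry other names. These have no locus and enter no comparison of genes.

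Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and figures were drawn with matplotlib. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Values are log2 differences, MYB87-SRDX minus wild type, with the standard error of the limma fit. A gene that was not well above background on any array of a group has only a bound there. The bound sets the mean of the brighter group against the mean, in the dimmer group, of the higher of the gene's own signal and the lowest signal of a probe well above background on that array.

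The 35 gene lists were fixed before the data were examined, and were tested with camera at an inter-gene correlation of 0.01, with adjustment over the lists. The gene table has no column of descriptions, so members were matched by symbol or synonym, and patterns meant for descriptions were matched to the full names that stand among the synonyms. Organelle-encoded transcripts were taken by locus. Families that the table names sparsely are covered in part. Over all lists, 61 entries share only a symbol with the genes meant, and the counts below include them unless stated. MYB87 was left out of the lists. The rule for the genes named was also fixed beforehand. It takes MYB87, and the 10 largest rises and 10 largest falls among genes past the threshold, well above background on all 8 arrays and with groups that do not overlap. It adds the 3 largest bounds in each direction, the 2 largest rises and falls in each of the cell wall family lists, and the largest rise and fall in each other list past its camera test. Members of lists named beyond this rule were chosen after their values were seen.

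All 4 wild-type arrays lay on one slide and all 4 MYB87-SRDX arrays on another, so slide and group cannot be told apart and no slide effect could be fitted. Per the labels, plants were grown with or without hygromycin, and the samples of the transgenic group were on hygromycin medium while the wild-type samples were not. The steps were tested on simulated values for 20262 genes, with the means and spreads of these arrays and 200 changed genes. Genes changed by log2 0.5, 1 and 2 were recovered in 34.3%, 77.6% and 95.5% of cases, with 5 false calls. The noise was drawn independently for each gene and no slide effect was added. These shares need not hold for the real arrays, where 5604 of 20336 genes passed.

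Alternatives comprised quantile and median scaling, normexp background correction (offset 50) before the 75th percentile scaling, the authors' values, other filters on dim probes, the mean of a locus's probes, other variance models, array weights, a replicate block, leaving out each array, other fold thresholds and other list tests. The normexp alternative used the median signal with the median background, since the mean signal was not used here, so it changes the signal together with the correction. Its planned fit failed on MYB87-SRDX replicate 4, where 9 spots had a local background over 2 times the median of the array. The normexp values given are from a run without such spots, added after seeing the data. An offset of 50 on the processed signal alone was added likewise, since the normexp run adds that offset.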

Results

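The data set compared whole 2-week-old Arabidopsis seedlings of wild type (n = 4) with seedlings expressing 35S:MYB87-SRDX (n = 4). MYB87 is an R2R3-type MYB transcription factor, and SRDX is a short repressor motif that turns an activator into a dominant repressor of its targets. The comparison asks which genes change when MYB87 fused to this motif is expressed from the 35S promoter, with cell wall genes as the named interest of the study. No group expressed MYB87 without SRDX, so effects of the repressor motif and of overexpression cannot be told apart. Seedlings grew under 16 h light and 8 h dark at 23 °C on medium with 1% sucrose. The transgenic samples were on hygromycin and the wild-type samples were not, and each group was hybridised on its own slide, so the values below compare the genotypes together with these conditions. The 75th percentile of the processed signal lay between 1539 and 2055 on the 8 arrays. Correlations across genes, which are not independent replicates, ran from 0.9754 to 0.9939 within wild type, from 0.989 to 0.9954 within MYB87-SRDX and from 0.9613 to 0.9829 between the groups.

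The MYB87 transcript itself (AT4G37780) was far higher in MYB87-SRDX than in wild type. Its log2 signal relative to the 75th percentile of the array was 4.85 ± 1.54 (SD, n = 4) in MYB87-SRDX and -6.80 ± 0.89 (SD, n = 4) in wild type, where it was well above background on 2 of the 4 arrays. The log2 difference was 11.65 ± 0.77 (SE), with an adjusted p of 0.000532 by limma. It was 9.25 with normexp background correction and 12.42 without MYB87-SRDX replicate 4. Probe sequences were not used here, so the value does not separate transcripts of the transgene from those of the MYB87 gene itself. MYB87-SRDX replicate 4 carried less of it, at 2.54 against 5.52 to 5.75 in the other replicates. The probe for SUP (AT3G23130), the flower gene SUPERMAN, also rose strongly. The SRDX motif derives from SUPERMAN, so this probe may read the transgene rather than the SUP gene. Its signal was not well above background on any wild-type array and was at least 3770-fold higher in MYB87-SRDX. The adjusted p was 0.000205 by limma, and the log2 difference with normexp was 9.51, less than the bound. SUP was also lowest on MYB87-SRDX replicate 4, at 2.28 against 5.44 to 5.63.

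**Figure D1:**
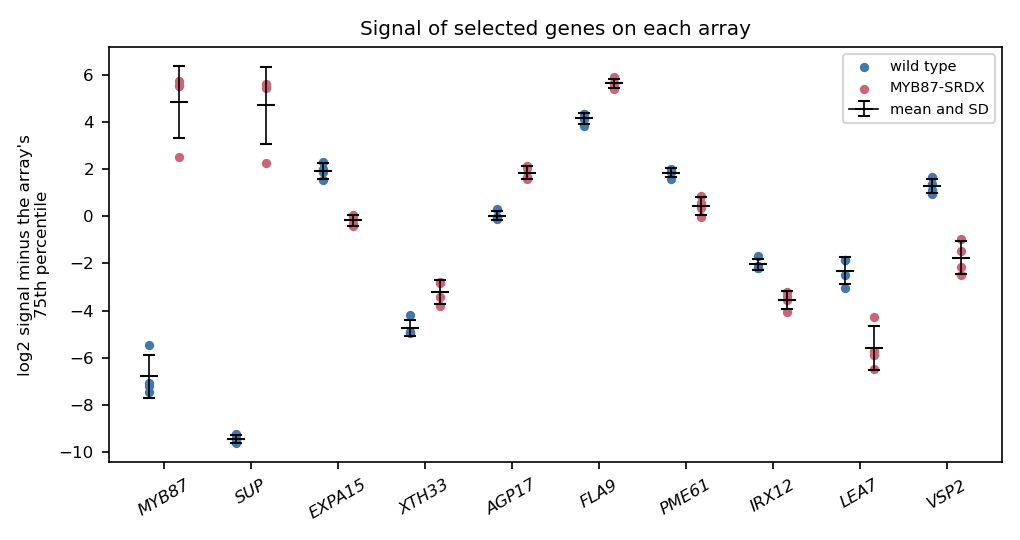
Log2 processed signal minus the array's 75th percentile for 10 genes, with a point per array, 4 per group, and the mean and SD as a bar. The MYB87 and SUP probes read far higher in MYB87-SRDX, with replicate 4 lowest at 2.54 and 2.28, and the SUP probe may read the transgene. IRX12, LEA7, VSP2, EXPA15 and PME61 are lower and XTH33, AGP17 and FLA9 higher.

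Among the largest falls, LEA7, a late embryogenesis abundant protein, fell by 3.28 ± 0.48 (SE) on the log2 scale, VSP2, a vegetative storage protein induced by jasmonate, fell by 3.05 ± 0.34, GSTF14, a glutathione transferase, fell by 2.67 ± 0.46, and CYP702A5, a cytochrome P450, fell by 2.66 ± 0.49. The other large falls were AT2G47880 (-3.25), AT3G54940 (-2.97), AT3G02480 (-2.95), AT1G52560 (-2.80), AT5G67430 (-2.78) and AT1G20070 (-2.69). Among the rises, PDF1.3, a plant defensin, rose by 3.02 ± 0.74, AACT1 rose by 2.92 ± 0.47, THA1, a threonine aldolase, rose by 2.65 ± 0.33, and AGL61, a MADS-box factor of the female gametophyte, rose 5.27-fold. The call of PDF1.3 was lost in 6 of 20 alternatives. The other large rises were AT3G55240 (3.29), AT5G61610 (2.45), AT2G41810 (2.39), AT5G62730 (2.38), AT3G21080 (2.38) and AT5G48430 (2.37). Normexp, which adds an offset of 50, made several of these log2 differences over 1.5 times smaller. Those of the falls became -2.03 for LEA7, -1.37 for CYP702A5, -1.53 for AT3G54940, -1.87 for AT3G02480 and -1.38 for AT1G52560. The rises became 1.53 for THA1, 1.39 for AGL61, 1.57 for AT5G61610, 1.25 for AT2G41810, 1.53 for AT5G62730 and 0.97 for AT3G21080. The seed genes PER1, a peroxiredoxin, and CRA1, a cruciferin, and the gene AT2G25890 were not well above background on any MYB87-SRDX array. They were at least 8.92-fold, 7.86-fold and 5.68-fold lower there, with adjusted p values of 0.00386, 0.0139 and 0.000777. With normexp their log2 differences were -1.47, -1.27 and -0.84, which is less than these bounds, and CRA1 lost its call. In the other direction, XTH25 and AT2G43890 were not well above background in wild type and were at least 4.09-fold and 4.06-fold higher in MYB87-SRDX. With normexp their log2 differences were 0.64 and 0.79, also less than the bounds.

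Over all genes, 5604 of 20336 differed at an adjusted p below 0.05 by limma, 3064 higher and 2540 lower in MYB87-SRDX. Of these, 372 were at least 2-fold higher and 494 at least 2-fold lower. The groups did not overlap for 30.8% of genes, where chance gives 2.86%. The number of calls depended on the processing. The authors' values gave 1102 higher and 1095 lower. Normexp, run on the median signal in place of the processed signal and without spots of high local background, gave 164 at least 2-fold higher and 211 at least 2-fold lower. An offset of 50 added to the processed signal alone gave 180 and 233. Median scaling gave 2675 higher and 1381 lower, a share of 66% higher against 54.7%. It moved the median log2 difference of all genes from 0.011 to 0.101. Leaving out wild type replicate 2 gave 2951 genes and leaving out MYB87-SRDX replicate 1 gave 3279, while without wild type replicate 3 the genes higher in MYB87-SRDX numbered 1923. Of the 50 named genes, 47 kept their call with that normexp setting, and CRA1, XTH29 and PERK4 lost it.

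Of the cell wall families, expansins, which loosen walls during growth, were more often lower than higher. Among 26 measured members 11 fell, 4 rose and 11 did not pass (12 lower and 4 higher when adjusted over the list alone). EXPA2, well above background on 1 of the 4 MYB87-SRDX arrays, fell by 2.51 ± 0.64 (SE) on the log2 scale, and by 0.72 with normexp. EXPA15 was 4.29-fold lower, with an adjusted p of 0.000731, while EXPA17 rose by 1.38 ± 0.40. EXPA12 was not well above background in wild type and was at least 2.19-fold higher in MYB87-SRDX, with a log2 difference of 0.53 with normexp, less than the bound. The list mean was -0.41, with a camera adjusted p of 0.00769, and adjusted p = 0.645 with an estimated correlation. Without a filter on dim probes its adjusted p was 0.0513. EXPA2 and EXPA17 lost their calls in 5 and 7 of their alternatives.

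Xyloglucan endotransglucosylase/hydrolases (XTHs), which cut and rejoin xyloglucan, moved the other way. Of 30 measured members 13 rose, 1 fell and 16 did not pass (14 higher and 5 lower when adjusted over the list alone). Besides XTH25, XTH33 rose by 1.53 ± 0.27 (SE), and by 0.90 with normexp. XTH24 rose by 1.52 ± 0.19. XTH29, well above background on 3 of the 4 MYB87-SRDX arrays, fell by 0.93 ± 0.17, and with normexp its difference was -0.15, not past the threshold. The list mean was 0.48, with a camera adjusted p of 0.02, and adjusted p = 0.891 with an estimated correlation. The adjusted p was 0.0575 without wild type replicate 3 and 0.0518 without wild type replicate 4. The wild-type list means varied from -0.60 to 0.17 relative to the mean of all arrays, and the root hair list varied from -0.59 to 0.86 over the same arrays.

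Arabinogalactan proteins, glycoproteins of the wall and membrane surface, included 13 members that rose and 6 that fell among 41 measured (16 higher and 6 lower when adjusted over the list alone). AGP17 rose by 1.83 ± 0.15 and the fasciclin-like FLA9 by 1.48 ± 0.15, while FLA10 fell by 1.07 ± 0.21 (0.58 with normexp) and FLA11 fell by 0.83 ± 0.16. The list did not pass its camera test, with an adjusted p of 0.0669. Its fry adjusted p was 0.0338, in the direction of a rise. Pectin methylesterases, which remove methyl groups from pectin, split into 5 members that rose and 2 that fell among 15 measured (5 and 3 when adjusted over the list alone). ATPMEPCRB rose by 1.57 ± 0.18 and AT2G26440 by 1.19 ± 0.15, while PME61 fell by 1.41 ± 0.19 and PME5 fell by 1.03 ± 0.23. The list's camera adjusted p was 0.418 and its fry adjusted p 0.0282, the latter in the direction of a rise. Of 6 members matched by name to pectin lyases and polygalacturonases, PG2 rose by 0.32 ± 0.09 (0.17 with quantile scaling) and PG1 fell by 0.85 ± 0.23. Adjusted over the list alone the counts were also 1 and 1, and the list's camera adjusted p was 0.49. Whether these members cut pectin was not checked. PG2 and PG1 lost their calls in 10 and 6 of 20 alternatives.

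Of 27 measured members of the list of extensins and proline-rich proteins, 2 rose and 3 fell. The counts were the same when adjusted over the list alone, and the list's camera adjusted p was 0.668. Besides structural proteins of the wall, the list holds 8 measured receptor kinases with the PERK stem and some loci matched by the PRP stem alone. Its counts therefore do not stand for structural proteins only. LRX3, a leucine-rich repeat extensin, rose by 1.31 ± 0.13 and the extensin-like ELP by 0.55 ± 0.08. The receptor kinase PERK4, not well above background on any MYB87-SRDX array, was at least 2.96-fold lower. With normexp its difference was -0.31, not past the threshold. PRP39, which shares the symbol stem but is known as a pre-mRNA processing factor, fell by 0.80 ± 0.23 and lost its call in 9 alternatives. None of 13 class III peroxidases, which crosslink or loosen walls, passed the limma test, over all genes or when adjusted over the list alone. At an unadjusted p below 0.05 there were 2. The list's camera adjusted p was 0.784, the fry adjusted p 0.902, and its list mean was -0.07, with 0.02 under median scaling. Relative to the mean of all arrays, its wild-type list means ran from -0.675 to 0.864, so a change within this spread could be missed.

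**Figure D2:**
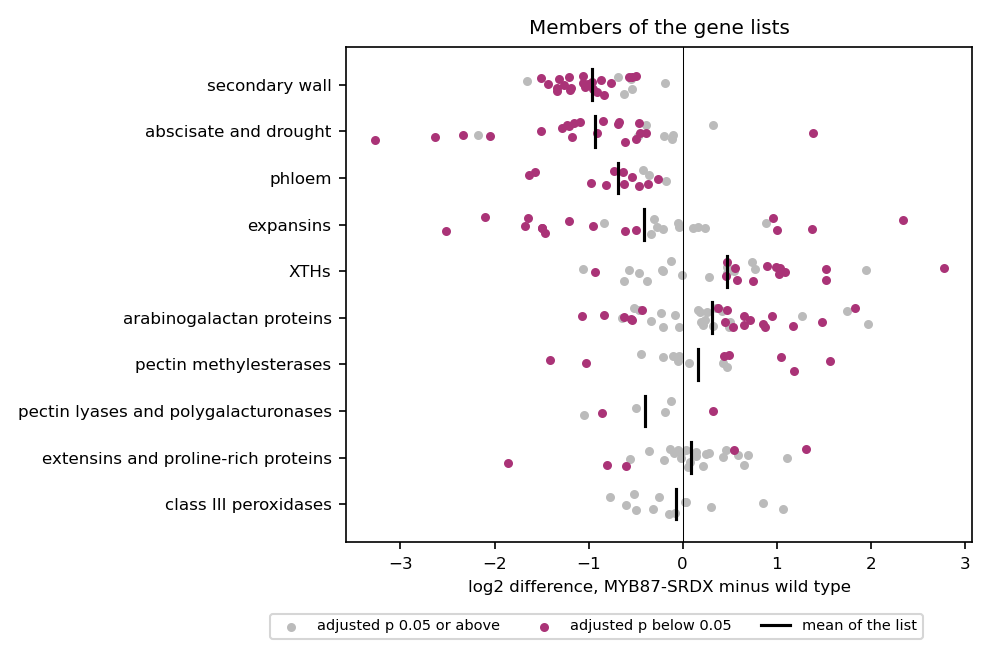
Log2 difference, MYB87-SRDX minus wild type, of each measured member of 10 gene lists, with coloured points for adjusted p below 0.05 by limma and a black bar for the list mean. Secondary wall members lie below 0 with a mean of -0.97, while XTHs have a mean of 0.48.

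Secondary wall genes, which build the thick walls of xylem and fibres, were lower in MYB87-SRDX. Of 28 measured members 22 fell, none rose and 6 did not pass (25 lower when adjusted over the list alone). IRX12, a laccase of lignin deposition, fell by 1.51 ± 0.19 (SE) and GAUT12 fell by 1.43 ± 0.16. The cellulose synthase gene CESA4 fell by 1.01 ± 0.16 and the regulator MYB46 fell by 0.91 ± 0.16. The list mean was -0.97, with a camera adjusted p of 1.54e-13, and adjusted p = 0.645 with an estimated correlation. Relative to the mean of all arrays, the list means in wild type were 0.93, 0.53, 0.25 and 0.23 in replicates 1 to 4, where the root hair list had 0.86, 0.34, -0.59 and -0.26, and those in MYB87-SRDX ran from -0.67 to -0.26. FLA11 and FLA12 stand both in this list and among the arabinogalactan proteins. In contrast, none of 9 primary wall cellulose synthesis genes passed the limma test, over all genes or the list alone, and 0 did at an unadjusted p below 0.05. The camera adjusted p was 0.527 and the fry adjusted p 0.638.

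Phloem markers were also lower, with 11 of 14 members falling and 3 not passing (11 lower when adjusted over the list alone). GLN1;4, a glutamine synthetase, fell by 1.63 ± 0.16, the sulfate transporter gene SULTR2;1 fell by 1.57 ± 0.21 and the sucrose transporter gene SUC2 fell by 0.97 ± 0.17. The list mean was -0.68, with a camera adjusted p of 2.05e-06, and adjusted p = 0.257 with an estimated correlation.

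Genes of abscisate and drought response were lower, with 20 of 28 measured members falling, 1 rising and 7 not passing (22 lower and 1 higher when adjusted over the list alone). Besides LEA7, COR15A, a cold-induced chloroplast protective protein, fell by 2.63 ± 0.32, and DREB1A, a transcription factor of cold response, fell by 2.34 ± 0.20. NAC3, a NAC transcription factor, rose by 1.39 ± 0.35 (0.91 with normexp), a call lost in 5 alternatives. The list mean was -0.94, with a camera adjusted p of 1.63e-10, and adjusted p = 0.249 with an estimated correlation.

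These 5 lists were the only lists of 35 past their camera test in the main setting, and none passed with an estimated correlation. All 5 passed by fry, with adjusted p values from 0.000361 to 0.0282. Without members that share only a symbol, 6 lists passed camera, among them 3 of the 10 tissue marker lists against 2 in the main setting. The arrays allow 35 splits into 4 and 4, and the exact permutation of a list's mean over them cannot give a p below 0.0286. Of the 35 lists 8 reached that p, with an adjusted p of 0.125. They were secondary wall, phloem, abscisate and drought and expansins, and 4 lists that did not pass camera, namely auxin response, axillary meristem and boundary, cytosolic ribosomal proteins and seed storage. Arabinogalactan proteins, pectin methylesterases, salicylate and pathogen response, flowering genes and XTHs had 0.0571, with an adjusted p of 0.154. The other splits of the arrays gave between 1 and 20 lists past the camera test at the preset correlation, with a median of 11.

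Among the tissue markers, photosynthesis genes had a list mean of 0.12 (4 higher and 2 lower of 59), with 0.21 under median and 0.01 under quantile scaling, root hair genes -0.17 (1 higher and 3 lower of 28), with -0.08 under median scaling, and root transporters -0.28 (1 and 3 of 16). None of 13 Casparian strip genes passed the limma test, over all genes or the list alone, with 1 at an unadjusted p below 0.05 and a fry adjusted p of 0.942, and 1 of 19 suberin genes fell. The Casparian strip means in wild type ran from -0.653 to 0.729 relative to the mean of all arrays, so a change within this spread could be missed. Guard cell markers had 4 lower of 15 and no higher. Seed storage and embryo genes had 5 lower and 1 higher of 9, with a mean of -1.24 that became -0.37 under normexp. Flowering and floral organ genes had 6 lower and 2 higher of 28, with a mean of -0.32 that became -0.16 under normexp. That list holds more than 1 locus for each of the symbols SEP1 and SEP2, so some members share only a symbol. FT, the mobile flowering signal, fell by 1.87 ± 0.20, FLC, a repressor of flowering, fell by 1.55 ± 0.20, and AGL8 fell by 2.44 ± 0.17, while SEP3, a floral organ factor, rose by 1.71 ± 0.44. The camera adjusted p values of these lists were 0.0859, 0.296, 0.292, 0.951, 0.892, 0.133, 0.128 and 0.0836 in the order given. By fry the seed storage and embryo list had an adjusted p of 0.0204, in the direction of a fall. Adjusted over the list alone, suberin had no call, guard cell markers 5 lower and 2 higher, flowering genes 6 lower and 4 higher, and the others the counts given.

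Auxin response genes had 28 lower and 14 higher of 104, with a camera adjusted p of 0.0611, and cytosolic ribosomal proteins had 4 higher and 1 lower of 7, also at 0.0611. By fry the auxin response list had an adjusted p of 0.0282, toward lower, and the ribosomal list 0.00504, toward higher. Jasmonate genes had 5 higher and 4 lower of 28. PDF1.2b, PDF1.2c and PDF1.3, defensins of the ethylene and jasmonate branch, rose by 2.96 ± 0.74, 2.96 ± 0.74 and 3.02 ± 0.74 (closely related sequences, which probes may not tell apart), while VSP2, a storage protein, and LOX2 and JMT, enzymes of jasmonate metabolism, fell by 3.05, 0.95 and 1.11. Salicylate and pathogen response genes had 4 lower and 1 higher of 18, cuticle genes 7 lower and 3 higher of 30, and glutathione transferases 5 lower and 2 higher of 40. Cell cycle genes had 9 lower and 4 higher of 61, and gibberellin genes 5 lower and 4 higher of 27. Brassinosteroid genes had 4 lower and 2 higher of 19. The aquaporin list, whose members may share only a symbol, had 4 lower and 5 higher of 44. The monolignol biosynthesis list had 3 lower and 4 higher of 22. It holds more than 1 locus for each of the symbols CCR1, CCR2 and FAH1, so some members share only a symbol. Axillary meristem and boundary genes had 2 lower and 4 higher of 20, and heat shock proteins 3 higher and 0 lower of 36. None of 17 members of the anthocyanin list and no MYB87 relative of 5 passed the limma test over all genes or the list alone. At an unadjusted p below 0.05 there were 1 and 0, with fry adjusted p values of 0.995 and 0.981. Relative to the mean of all arrays, their wild-type list means ran from -0.369 to 0.423 and from -0.62 to 0.695. A change within such a spread could be missed. The anthocyanin list takes in loci that share only a symbol, such as further loci named PAP1, so its members are not all anthocyanin genes. Of 4 organelle-encoded transcripts, 1 fell. The camera adjusted p values of the lists from jasmonate to organelle-encoded transcripts ran from 0.215 to 0.967. Of these lists, salicylate and pathogen response passed by fry, with an adjusted p of 0.0433, toward lower. Adjusted over the list alone, auxin response had 30 lower and 15 higher, ribosomal proteins 1 lower and 5 higher, jasmonate 5 lower and 5 higher, salicylate 4 lower and 2 higher, glutathione transferases 5 lower and 0 higher, cell cycle 7 lower and 4 higher and heat shock proteins 0, and the other lists had the counts given.

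**Figure D3:**
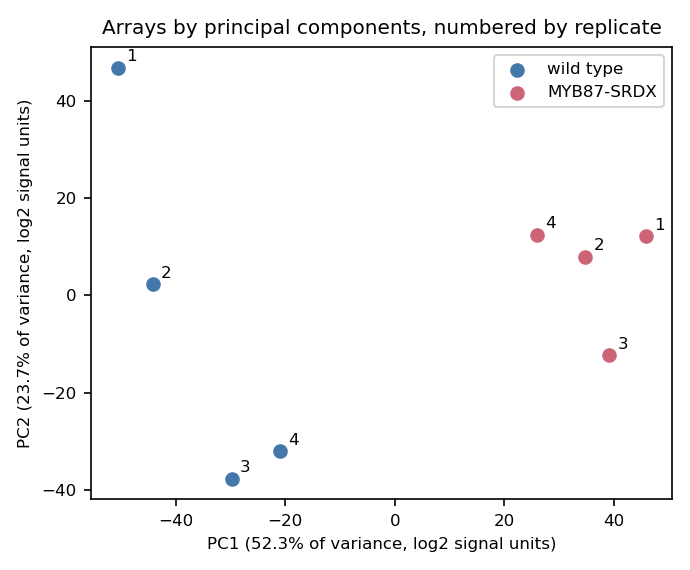
Principal components of the 8 arrays over all tested genes, numbered by replicate. PC1, with 52.3% of the variance, separates MYB87-SRDX from wild type, and PC2, with 23.7%, spreads the wild-type arrays from -37.6 to 46.8.

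On the second principal component wild type replicates 1 to 4 lay at 46.8, 2.39, -37.6 and -31.9. Replicate 1 is thus an end of a spread and not an array apart from the rest. MYB87-SRDX replicate 4 stood apart in the level of MYB87. Leaving out both wild type replicate 1 and MYB87-SRDX replicate 4 gave 4572 genes by limma, 2205 higher and 2367 lower in MYB87-SRDX. The MYB87 difference was then 12.86.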

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

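The tests on other splits of the arrays were set before their results were seen. The tests on the control transcripts, on SUP and on the root marker lists were chosen only after the result was seen. A sample far from the others of its group was sought in 170 groups of values, where chance gives about 1 in 20, and 13 were found.

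Among genes, MYB87-SRDX replicate 4 lay apart for MYB87 at 2.54, for SUP at 2.28, for AT2G47880 at -4.99, for PG1 at -0.53 and for PERK4 at -6.86, each on the log2 scale relative to the 75th percentile of the array. Wild type replicate 1 lay apart for XTH33 at -4.21 and for PME5 at 1.51, wild type replicate 3 for AT5G48430 at -4.03, and wild type replicate 4 for AT3G21080 at -5.52 and AT2G43890 at -7.87. Among list means, relative to the mean of all arrays, the cuticle list lay apart in wild type replicate 1 at -0.13 and in MYB87-SRDX replicate 1 at -0.11, and the cell cycle list in MYB87-SRDX replicate 3 at 0.23.

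Probes without a gene locus enter no comparison of the report. Of 3203 tested, 619 were higher and 189 lower in MYB87-SRDX by limma, with 190 and 35 of them at least 2-fold.

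SUP and MYB87 moved together over the MYB87-SRDX arrays. A candidate explanation is that the SUP probe reads the SRDX motif of the transgene, which derives from SUPERMAN, or sequence attached to it. In that case both probes would show the same dips, and the deviations of the 2 genes from their own MYB87-SRDX means differed by at most 0.131 on the log2 scale on any of the 4 arrays. Transcription of SUP itself stays open. PI, a floral gene that SUP restricts, differed by 0.825 with an adjusted p of 0.0517, and the probe sequences were not used here, so these explanations cannot be told apart by that gene.

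The real grouping gave the most changed genes of the 35 splits of the arrays, a rank with p = 0.0286 by exact permutation, the smallest possible. Of 35 splits, 1 gave as many as the real 5604 genes, the real one itself, and the highest other split gave 76. For genes changed at least 2-fold the real split gave 866, again 1 of 35, and the highest other gave 9. Every other split mixes the genotypes, which adds their difference to the spread within its groups. The low counts of those splits therefore add little to the rank. For gene lists past the camera test, 31 of the 35 splits gave as many as the real 5, and the highest other gave 20, so chance cannot be excluded for that count. A hybridisation or scanning shift shared by probes of like brightness was tested on 8 spiked control transcripts. Their largest difference between the slides was 0.359 after scaling. This argues against such a shift for changes of at least 2-fold within the brightness range of the controls, which held 74.1% of them. It cannot decide for the 1632 called genes with changes no larger than 0.359, and changes in between were not judged. Other slide effects, hygromycin and any other difference in growth or handling between the groups stay open. This holds for all changes other than that of MYB87, the gene the construct carries. Without a group expressing MYB87 alone, overexpression and the repressor motif cannot be told apart either.

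The root marker lists differed between wild-type replicates. The 76 genes of the root hair, Casparian strip, suberin and root transporter lists deviated from the wild-type mean by 0.70, 0.29, -0.69 and -0.30 in replicates 1 to 4, against 0.05, 0.21, -0.29 and 0.04 in MYB87-SRDX. Array position on the slide cannot be told apart from the samples. The slope of the MYB87-SRDX deviations on the wild-type deviations at the same positions was 0.247 ± 0.162 (SE over the 4 positions), where a position effect was taken to need 0.5 or more, and 4 positions are too few to exclude it. A different share of root tissue in the harvested seedlings may be the source. The 4 lists would then deviate alike in each wild-type array, and the largest difference between lists was 1.9 standard errors over genes. In MYB87-SRDX replicate 3 the Casparian strip list deviated by -0.72 and the suberin list by 0.03, so the lists do not always move together.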

How the results depend on the processing

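The normexp run without spots of high local background and the offset on the processed signal were chosen after seeing the data. So were leaving out wild type replicate 1 and MYB87-SRDX replicate 4, the lists without members that share only a symbol, and the exact permutation. MYB87 kept its direction and call in all 19 alternatives, from 9.25 with normexp to 12.86, and from 11.35 to 12.42 when each array was left out.

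The planned normexp fit failed on MYB87-SRDX replicate 4. There 9 spots had a local background over 2 times the array's median, up to 27603. The fitted background mean was -526, against 9 to 10.6 on the other MYB87-SRDX arrays and -5.4 to -2 on the wild-type arrays. That run gave 1236 genes, 765 higher and 471 lower, with 157 and 92 at least 2-fold, left 22 of the 50 named genes past the threshold, and turned the sign of XTH29 at 0.53 and PERK4 at 0.36. These values are void and enter no other count. Without such spots the fitted mean was 12.3, and 5534 genes passed, 3183 higher and 2351 lower, with 164 and 211 at least 2-fold. An offset of 50 added to the processed signal alone gave 180 and 233, so the offset by itself gives most of that drop from 372 and 494. Of the named genes 47 kept their call with normexp and 48 with the offset.

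Counts also moved by over 1.5 times in these settings, and the cause was not tested except where fewer arrays or a stricter threshold is the setting itself. The authors' values gave 2197, 1102 higher and 1095 lower. Median scaling gave 1381 lower. Requiring 1.5-fold as well gave 2160, 888 higher and 1272 lower, and the treat test against 1.5-fold gave 182, 82 higher and 100 lower. Leaving out each array gave 2951 to 6006 genes, 1576 to 3109 higher and 1375 to 2897 lower, with 274 to 455 and 357 to 572 at least 2-fold.

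Of the 35 lists, 5 passed in the main setting, 8 with the authors' values and 8 with array weights. Leaving out both wild type replicate 1 and MYB87-SRDX replicate 4 also gave 8. Without members that share only a symbol 6 passed. By fry 11 passed. They were the 5 lists of the main setting, arabinogalactan proteins, pectin methylesterases, auxin response, cytosolic ribosomal proteins, salicylate and pathogen response, and seed storage. With an estimated correlation 0 passed, and by exact permutation, whose smallest p is 0.0286, also 0. Leaving out each array gave 4 to 9. Of the 10 tissue marker lists, 2 passed in the main setting and 3 without members that share only a symbol. There were 4 without both wild type replicate 1 and MYB87-SRDX replicate 4, and 2 to 4 when each array was left out. With an estimated correlation or exact permutation there were 0. Adjusted p values were 0.645, 0.891, 0.645, 0.249 and 0.257 with an estimated correlation for expansins, XTHs, secondary wall, abscisate and drought, and phloem, and 0.125, 0.154, 0.125, 0.125 and 0.125 by exact permutation. Expansins had 0.0513 without a filter. Leaving out each array gave 0.00177 to 0.0281 for expansins and 0.00179 to 0.0575 for XTHs, and secondary wall, abscisate and drought, and phloem stayed past the threshold.

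With the replicate block 3612 genes passed, 1812 higher, and no call of a list changed. The labels do not say that the numbers pair the samples. The deviations of same-numbered samples correlated across genes at 0.095, 0.09, 0.16 and -0.22. Wild-type replicates 2 and 3 correlated best with their own number and 1 and 4 with another. Such correlations cannot show whether the samples were paired. A slide block could not be fitted, since each slide holds one group. Of single named genes under alternatives, 936 of 989 values kept their call, 53 lost it and 0 reversed. Dim signal limits genes near background. The median local background was 63 to 64 on the wild-type slide and 52.5 to 54 on the MYB87-SRDX slide, so it differs with group.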

Other observations

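The symbol family and control transcript values were chosen after seeing the data. Among 212 families of genes sharing a symbol stem, with at least 8 tested members, 11 passed camera after adjustment over the families, and none with an estimated correlation. Genes with the IAA stem, early repressors of auxin response, had 13 of 23 members lower and 0 higher by limma. Their mean was -0.41, with a camera adjusted p of 0.000602 and 0.942 with an estimated correlation. Aux/IAA genes that carry another symbol are not counted here. IAA29 fell by 1.98 ± 0.25 (SE), IAA6 fell by 1.09 ± 0.30 and IAA19 fell by 0.44 ± 0.14. The family mean lay below 0 under every scaling run, from -0.30 with normexp to -0.43 with the authors' values. Genes with the IQD stem, calmodulin-binding scaffold proteins, had 11 of 32 lower and 1 higher, with a mean of -0.28, an adjusted p of 0.0267 and adjusted p = 0.942 with an estimated correlation. The mean ran from -0.19 with median scaling to -0.30 with the authors' values, and IQD10 fell by 1.14 ± 0.17. Genes with the RPS stem, mostly ribosomal proteins of the small subunit, had 11 of 24 higher and 1 lower, with a mean of 0.20, an adjusted p of 0.0246 and adjusted p = 0.942 with an estimated correlation. The mean ran from 0.15 with quantile to 0.29 with median scaling. The lower member, RPS2 (AT4G26090), shares only the symbol and is a disease resistance gene.

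Genes changed at least 2-fold, other than MYB87 and SUP, had median log2 changes in the direction of their call of 1.60, 1.40, 1.39 and 1.28 in MYB87-SRDX replicates 1 to 4, over 864 genes, while MYB87 in replicate 4 lay 2.31 below its group mean on the log2 scale. The genes were selected for their change on these same arrays, replicate 4 included, which by itself keeps the medians high. The medians therefore cannot show whether the changes follow the level of MYB87. All 8 spiked control transcripts were higher relative to the 75th percentile on the MYB87-SRDX slide, by 0.117 to 0.359 with a median of 0.306. No scaling run used these controls. Rises of that size, such as the RPS mean of 0.20, and the split into higher and lower genes therefore depend on the choice of scaling.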
